A study of Mus musculus with 12 samples.

How the data were processed

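Total RNA from the dentate gyrus of C57BL/6 mice was sequenced in 12 libraries, 3 in each of 4 groups. The groups were taken from the descriptions: WT, KO of Fst, KO with an AAV9 vector for GFP, and a group called overexpressing with an AAV9 vector for Fst. The sources state no genotype for that last group. Titles and descriptions give different sexes for KO F1, KO M2, WT F1 and WT M2; libraries are named here as in the titles and none was moved between groups. The design text can be read as several mice per library or per group, so whether libraries are pools is open.

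The authors deposited raw read counts per Ensembl gene in a table for WT and KO and another for the vector groups, per the file headers. The genome build was GRCm38, per the submitters' processing notes. The aligner, the counting tool, the annotation, the handling of strand and any removal of ribosomal RNA are not given in the sources used here. Each table held 52636 genes. There were also 12 lines in the vector table, and 6 in that of WT and KO, that name no gene; these were blank or held annotation text, carried no counts and were left out. Coordinates and symbols came from the GENCODE annotation of GRCm38, which gave coordinates for 52489 gene IDs and symbols for 52403. Without strand, reads of overlapping genes cannot be told apart, and reads shared by near-identical copies make haemoglobin, histocompatibility and ribosomal protein genes uncertain.

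Total counts per library ran from 8081824 to 11331337. CPM, counts scaled by these totals, were computed from the deposited counts, and a count of 3, the floor used here, equals 0.265 to 0.371 CPM. Intervals and floors cover counting error only. Chi-square per degree of freedom between replicates of a group was 2.49 to 34.7 over their counts, so no pair of libraries agreed within sampling noise.

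KO was compared with WT, and the Fst vector group with the GFP vector group, each on its own 6 libraries, because the tables were deposited separately. The test was edgeR's quasi-likelihood test (edgeR 4.0.16, R 4.3.3) with TMM scaling, the default filterByExpr, robust dispersion and Benjamini-Hochberg adjustment at 0.05. The SE of a log2 change is its size divided by the square root of F. The difference of the effects, Fst vector minus GFP vector less KO minus WT, was tested in 1 fit of all 12 libraries, as was GFP vector against KO, where the vector and the table cannot be told apart. Fold changes of the comparisons were correlated across genes, and shared calls were compared with the number expected for independent lists by Fisher's exact test.

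The comparisons share replicate names, so a fit with the replicate as a block was run beside each. Deviations from the group means were correlated for each pair of libraries. In the vector comparison the correlations of same-named libraries were 0.316 for M1, 0.113 for M2 and 0.353 for F, all above 0.1. The numbers were taken to pair the libraries. GFP M2 correlated slightly better with Fst F, at 0.118, and GFP M1 with Fst M2 also passed, at 0.103. Between KO and WT, WT F1 with KO M2 (0.144) and WT M2 with KO M1 (0.135) passed too. The bound of 0.1 alone thus does not identify pairs. GFP M2, Fst M2 and Fst F also had the higher share of ribosomal RNA, so the value for M2 need not reflect pairing. This pairing comes from the data, since no label states it. GFP F and Fst F are also the female libraries of the vector groups. Sex by title as a term called 132 genes there, against 141 with the block. More calls with the block are thus no evidence of paired mice.

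Gene lists were tested with limma's camera (limma 3.58.1) with voom weights and a preset correlation of 0.01, and again with an estimated correlation and with fry, adjusted over lists. The 42 lists were markers of mature granule cells, newborn neurons, neural stem cells, mossy cells, interneurons, Cajal-Retzius cells, CA1 and CA3 with CA2 pyramidal cells, astrocytes, reactive astrocytes, oligodendrocytes and their precursors, microglia, T cells, endothelial and mural cells, meningeal fibroblasts, choroid plexus, ependyma, blood, neocortex, striatum, and thalamus with habenula; activin, BMP and TGF-beta pathway members, SMAD response, Wnt and Notch response, interferon response, antigen presentation, glucocorticoid response, immediate-early genes, proliferation, heat shock with dissection stress, neuropeptides with growth factors, synaptic vesicle release, channels, receptors for glutamate, GABA and monoamines, nuclear oxidative phosphorylation, mitochondrially encoded genes, cytosolic ribosomal proteins, replication-dependent histones, and sex-linked transcripts. Lists needed at least 3 tested members. The T cell list had too few, and sex-linked transcripts served only to check labels, which left 40. In 7 lists of each comparison, none of them called, the median and the mean differed in sign. For neocortex in the vector comparison, not called either, both were negative (-0.0613 and -0.0139) while the test gave the higher direction. The heat shock list holds Hsp90aa1 and the ribosomal list Rpl12, both among the genes whose levels follow the rRNA share of a library.

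Groups, tests, alternatives, lists and the rule for naming genes were chosen before the data were examined. The rule named Fst, then called genes with a mean of at least 1 CPM and no overlap between the groups' libraries, at most 12 per direction, then, where fewer than 10 passed, the 5 with the smallest p in each direction, and up to 4 members of each list. Predicted gene models with clone-like symbols were counted but not named, and some list members that the rule names are not reported here. In the vector comparison Pmepa1, Asic4, Acvr1c, Cdhr1, Hpca and Sox1 are given outside the rule, chosen after their values were seen.

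Alternatives were RLE scaling, library totals alone, DESeq2 1.42.0, no filter, a filter of at least 1 CPM in 3 libraries, the replicate block, sex by title or description, a spread shared over 12 libraries, a tested minimum change of 1.2 fold, and leaving out each library. Added after seeing the data were the rRNA share as a term, leaving out the genes that follow it, offsets for GC content and length (splines with 5 degrees of freedom), leaving out both F libraries of the vector groups, and a contrast of follistatin present against absent in both tables. The list test with an estimated correlation and the block, in the vector comparison, was also added then. In the search for words shared with rRNA, the reference was corrected after a first run, because it had included a pair of the processed pseudogenes under study.

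The tests were tested on simulated data with 200 changed genes among counts drawn from the real means. In KO against WT (14736 genes), 67.2, 82.1 and 97% of changes of 1.5, 2 and 4 fold were recovered, and 22 of 186 calls (11.8%) were unchanged genes. In the vector comparison (14793 genes) these were 4.5, 41.8 and 93.9%, with 11 of 104 calls (10.6%) unchanged. With the block, 31 of 198 (15.7%) and 13 of 104 (12.5%) calls were unchanged genes, so all 4 shares lay above the nominal 5%. The test of the difference (15431 genes) recovered 6, 38.8 and 86.4%. With fewer calls the adjustment sets a stricter cut on p. The recovered shares may thus be too high for the real comparisons, which called 4 and 12 genes. The list test called 4 of 4 moved lists and 0 of 36 others in each comparison. The simulated genes were drawn independently of each other. In the real vector comparison the estimated correlation was 0.76 for interferon response and 0.88 for reactive astrocyte genes. The 0 of 36 therefore does not measure false calls among correlated genes.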

Results

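Transcript levels were measured by bulk RNA sequencing of total RNA from the dentate gyrus, the granule cell region of the hippocampus, of C57BL/6 mice. There were 4 groups of 3 libraries. They were wild type (WT), knockout of the follistatin gene Fst (KO), knockout given an AAV9 vector that carries green fluorescent protein (GFP vector), and mice given such a vector carrying Fst (Fst vector). The labels call the last group overexpressing without stating its genotype. Follistatin is a secreted protein that binds activins and keeps them from their receptors. Libraries held 8081824 to 11331337 counts, with 20915 to 22235 genes detected in each. Ribosomal RNA made up 0.563 to 0.658% of the counts in KO M2, WT F1, GFP M2, Fst M2 and Fst F, and 0.0086 to 0.0202% in the 7 other libraries. The sources leave open how many mice each library holds, so p-values measure the spread between these libraries. Xist, the transcript of the inactive X chromosome, stood at 1214 to 1785 CPM in KO F1, WT F1, GFP F and Fst F, and at 0.525 CPM or less in the 8 other libraries. The Y-linked transcript Ddx3y stood at 46.4 to 62.7 CPM in those 8 and at 0 in the libraries with Xist, so each of the 12 libraries held the transcripts of the sex in its title. The descriptions of KO F1, KO M2, WT F1 and WT M2 give the other sex.

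Fst was low in every KO library and high in every library of the Fst vector. The gene (ENSMUSG00000021765) lies on the minus strand of chromosome 13 at 114452290 to 114458951 in GRCm38. In WT, Fst counts were 34 in M1, 33 in F1 and 51 in M2, a mean of 3.87 ± 0.547 CPM (SD, n = 3). In KO they were 2, 4 and 2, a mean of 0.282 ± 0.127 CPM (SD, n = 3). WT stood 13.9 times above KO by summed counts, 118 against 8, with an exact 95% interval of 6.84 to 33.0 that covers counting error only. The log2 change in KO was -3.71 ± 0.42 (SE, edgeR quasi-likelihood, adjusted p = 1.13e-05). In the GFP vector group, Fst had 0, 1 and 0 counts. In the Fst vector group it had 2078, 1870 and 1497 counts, a mean of 186.4 ± 19.3 CPM (SD, n = 3). The Fst vector group exceeded the GFP vector group 5396 times by summed counts, with an exact 95% counting interval of 968 to 213179 (edgeR quasi-likelihood, adjusted p = 8.38e-07). Its mean CPM was 48.2 times that of WT, a ratio across tables deposited separately. Whether reads of the vector's insert were assigned to the chromosomal gene is not given in the sources used here.

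**Figure D1:**
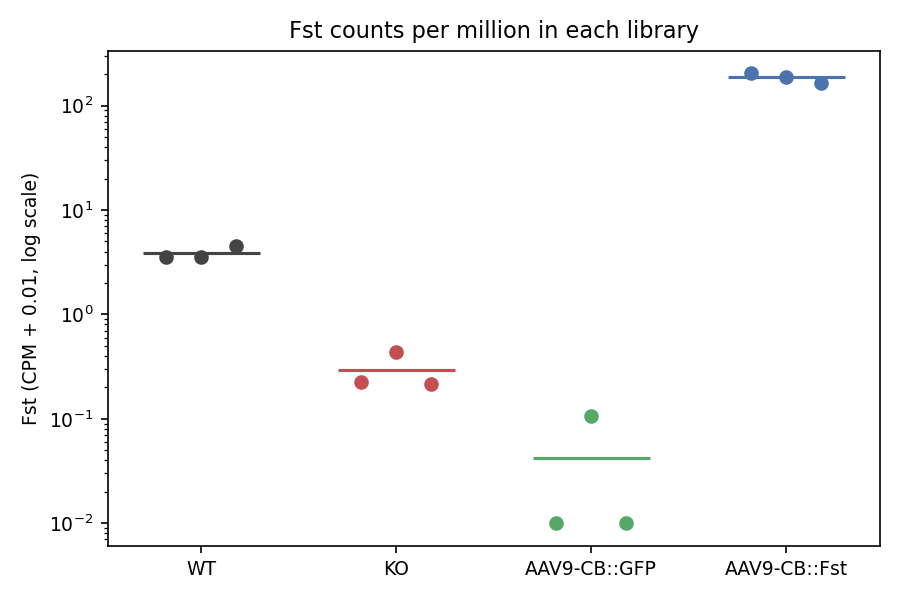
Fst level in each library, in CPM plus 0.01 on a log axis, with 3 points per group for its libraries and a line at each group's mean. The Fst vector libraries lie at 165.7 CPM or above, WT at 3.54 to 4.50 CPM and KO at 0.428 CPM or below.

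Loss of Fst went with few changes in the dentate gyrus. In the fit without a term for sex or replicate, 3 genes besides Fst differed between KO and WT, each with no overlap between the groups' libraries. Asic4, a member of the acid-sensing ion channel family (chromosome 1, 75450436 to 75474343), fell from 30.2 ± 5.04 CPM in WT to 16.1 ± 2.73 CPM in KO (SD, n = 3 each), a log2 change of -0.89 ± 0.13 (SE, edgeR quasi-likelihood, adjusted p = 0.0024). Sox1, a transcription factor of neural progenitors (chromosome 8, 12395295 to 12400126), fell from 10.4 ± 2.40 to 5.06 ± 0.555 CPM, a log2 change of -1.03 ± 0.19 (edgeR quasi-likelihood, adjusted p = 0.0259). Hpca, which encodes the neuronal calcium sensor hippocalcin (chromosome 4, 129111570 to 129122036), rose from 1030 ± 23.7 to 1271 ± 56.7 CPM, a log2 change of 0.32 ± 0.06 (edgeR quasi-likelihood, adjusted p = 0.0134). Sox1 lies inside Sox1ot, a transcript annotated on the same strand, and their reads cannot be told apart where they overlap; Sox1ot had a log2 change of -0.68 ± 0.16.

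Of the 14919 genes tested in KO against WT, edgeR's quasi-likelihood test called 4 at adjusted p under 0.05, 1 higher and 3 lower, and DESeq2 called 3. With sex by title as a term edgeR called 30, and with the replicate block 23. At unadjusted p under 0.05 there were 889 genes, 440 higher and 449 lower, where 746 are expected by chance. Scaling by library totals in place of TMM moved the higher share of these from 49.5% to 34.4%. The groups did not overlap for 11.02% of genes, where chance gives 10%. The 5 genes with the smallest p in each direction among those that did not pass the adjustment were these. The higher ones were Acvr1c, an activin receptor of type I, at 0.43 ± 0.09 on the log2 scale (adjusted p = 0.0584, edgeR quasi-likelihood), Eps8l1 at 0.67 ± 0.14, Fosl2 at 0.34 ± 0.07, Ndufb1-ps at 0.51 ± 0.11 and Cacna1g, a T-type calcium channel, at 0.49 ± 0.10. The lower ones were Col6a4 at -1.03 ± 0.20, Reln, which encodes reelin, at -0.37 ± 0.08, Selenop at -0.26 ± 0.06, Cdhr1 at -0.64 ± 0.14 and Sox1ot. The count rose to 17 without WT F1 and to 7 without KO M2, and fell to 2 without WT M2. The call of Sox1 ended in DESeq2 (adjusted p = 0.157) and without KO M1 (0.113), KO F1 (0.0676), KO M2 (0.115), WT M1 (0.220) or WT M2 (0.145). That of Hpca ended without WT M1 (0.0565) or WT M2 (0.304). Over all alternatives adjusted p ran from 1.53e-04 to 1 for Sox1, from 7.40e-07 to 1 for Hpca and from 5.08e-11 to 1 for Asic4. With a spread shared over 12 libraries the adjusted p of Asic4, Sox1 and Hpca was 1, and with a tested minimum change of 1.2 fold Sox1 (0.205) and Hpca (1) lost their calls.

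Among the gene lists fixed for the tissue, 9 of 40 moved in KO against WT by limma's camera with a preset correlation of 0.01, 4 higher and 5 lower. With an estimated correlation 0 did, and 2 passed at unadjusted p under 0.05. By fry, 0 lists passed and 3 did so unadjusted. Cajal-Retzius cell markers were lower, 8 of 8 members having a negative log2 change (camera adjusted p = 2.01e-05, adjusted p = 0.271 with an estimated correlation). Adjusted over the list alone, 4 of them were lower and 0 higher, with Reln at -0.37 ± 0.08, Ndnf at -0.34 ± 0.11, Trp73 at -0.53 ± 0.18 and Cacna2d2 at -0.33 ± 0.13, and 0 were called over all genes. Glucocorticoid-responsive genes were lower in 15 of 16 members (camera adjusted p = 2.01e-05, adjusted p = 0.434 with an estimated correlation). Adjusted over the list alone, 4 were lower: Map3k6 at -0.94 ± 0.24, Plin4 at -0.72 ± 0.23, the clock gene Per1 at -0.18 ± 0.06 and Tsc22d3 at -0.39 ± 0.13. Potassium, sodium and calcium channel genes were higher in 23 of 31 members (camera adjusted p = 2.35e-05, adjusted p = 0.434 with an estimated correlation), with 2 higher adjusted over the list alone, Cacna1g among them. Synaptic vesicle release genes were higher in 21 of 25 members (camera adjusted p = 1.63e-04, adjusted p = 0.434 with an estimated correlation) and 0 members passed adjusted over the list alone, Stx1a having 0.17 ± 0.08. These 4 lists kept their calls without any 1 of the 6 libraries.

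The other 5 lists covered meningeal fibroblasts, blood, antigen presentation, heat shock with dissection stress, and nuclear oxidative phosphorylation. Meningeal fibroblast markers were lower in 17 of 19 members (camera adjusted p = 2.84e-04, adjusted p = 0.585 with an estimated correlation), with Slc13a4 at -1.12 ± 0.35 and 0 members adjusted over the list alone. Blood transcripts were lower in 5 of 5 members (camera adjusted p = 0.0034, adjusted p = 0.482 with an estimated correlation), with the haemoglobin gene Hbb-bs at -0.48 ± 0.14 as the 1 member adjusted over the list alone. Antigen presentation genes were lower in 11 of 14 members (camera adjusted p = 0.0378, adjusted p = 0.434 with an estimated correlation), with H2-D1, a class I histocompatibility gene, at -0.40 ± 0.10 as the 1 member adjusted over the list alone. Counts of haemoglobin and histocompatibility genes are uncertain, because near-identical copies share reads. Heat shock and dissection stress genes were higher in 10 of 14 members (camera adjusted p = 0.0025, adjusted p = 0.482 with an estimated correlation), and 3 passed adjusted over the list alone: Hspa8 at 0.20 ± 0.06, Hspe1 at 0.23 ± 0.08 and Hspa1b at 0.41 ± 0.14. Nuclear genes of oxidative phosphorylation were higher in 46 of 79 members (camera adjusted p = 0.0079, adjusted p = 0.482 with an estimated correlation), with Cox7c at 0.21 ± 0.06 and 0 adjusted over the list alone. Calls ended without WT F1 for blood (adjusted p = 0.0900), antigen presentation (0.217) and oxidative phosphorylation (0.116). They ended without KO M1 for blood (0.0563) and antigen presentation (0.137), and without KO F1 for antigen presentation (0.0768). They ended without WT M2 for meningeal fibroblasts (0.168) and heat shock (0.0997). Over all alternatives the highest adjusted p of these 5 lists lay between 0.483 and 0.650 and the lowest between 5.76e-12 and 0.0098. Antigen presentation also lost its call with scaling by library totals (0.0609), and without KO M2 the number of lists rose to 14.

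Markers of newborn neurons did not pass as a list in KO against WT (24 members, camera adjusted p = 0.146), although 3 of them were lower adjusted over the list alone: Dcx, the microtubule protein doublecortin, at -0.41 ± 0.11, Igfbpl1 at -1.14 ± 0.31 and Draxin at -1.41 ± 0.40. Genes that respond to SMAD signalling did not pass (19 members, adjusted p = 0.892), with 1 lower, Id4 at -0.22 ± 0.07, and 1 higher, Pmepa1 at 0.33 ± 0.10, adjusted over the list alone. Ligands, receptors and antagonists of the activin, BMP and TGF-beta pathways did not pass either (41 members, adjusted p = 0.789), with Acvr1c as the 1 higher member adjusted over the list alone. Other lists that did not pass had 1 to 3 members past the test adjusted over the list alone. These were Oasl2 at -1.03 ± 0.29 among interferon response genes (adjusted p of the list = 0.0521) and Sox1 among neural stem cell genes (0.326). Plk5 had 0.26 ± 0.06 among mature granule cell genes (0.587) and Nrgn 0.20 ± 0.05 among mossy cell genes (0.603). Interneuron genes had 2 lower members, Reln among them (0.143). Fosl2 was higher and Sik1, at -0.52 ± 0.14, lower among immediate-early genes (0.789). There were Dkk3 at 0.43 ± 0.10 among CA1 pyramidal genes (0.941), and Dkk3, Dll1 at -0.56 ± 0.18 and Dll3 at -1.08 ± 0.34 among Wnt and Notch response genes (0.439). The remaining lists did not pass by camera and had 0 members adjusted over the list alone. Their adjusted p was 0.0757 for proliferation (with Top2a at -1.10 ± 0.36), 0.0960 for astrocytes and for neuropeptides with growth factors, 0.1004 for histones and 0.189 for GABA receptors. It was 0.326 for thalamus and habenula, 0.352 for CA3 and CA2 pyramidal cells, 0.366 for ependyma, and 0.451 for microglia and for monoamine receptors. It was 0.590 for oligodendrocyte precursors, 0.656 for cytosolic ribosomal proteins, 0.718 for mitochondrially encoded genes, and 0.789 for neocortex and for oligodendrocytes. It was 0.805 for reactive astrocytes, 0.871 for choroid plexus, 0.892 for glutamate receptors, 0.922 for striatum and 0.970 for endothelial and mural cells.

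**Figure D2:**
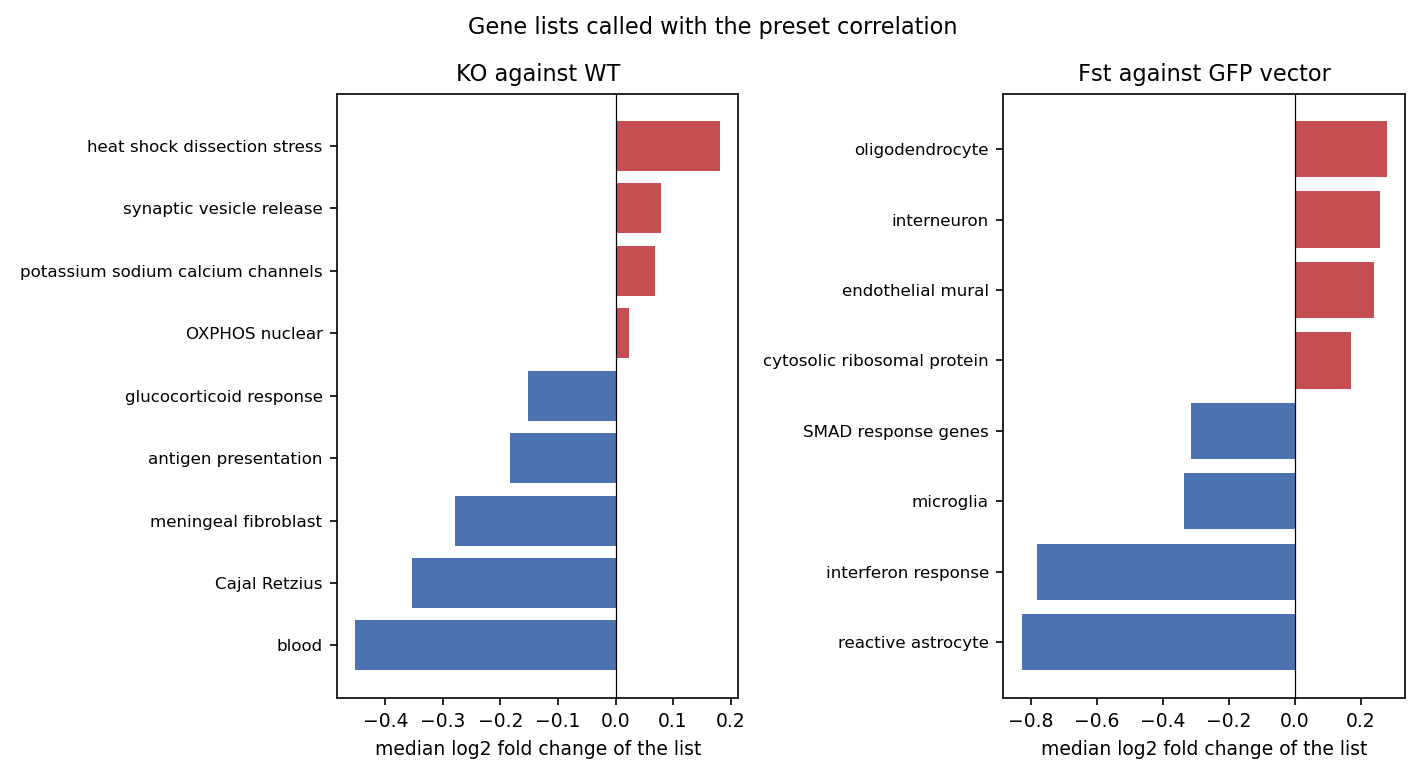
Median log2 change of the tested members of each gene list that camera called with the preset correlation, as bars from 0, for KO against WT (left, 9 lists) and Fst vector against GFP vector (right, 8 lists), with the scales of the panels set separately. Reactive astrocyte and interferon response genes have the lowest medians of the vector comparison, -0.83 and -0.78, and no list is called with an estimated correlation.

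The vector comparison asks which transcripts differ between animals given Fst and animals given GFP. Besides Fst, 11 genes differed, 3 higher and 8 lower, each with no overlap between the groups' libraries. Robo3, an axon guidance receptor (chromosome 9, 37415669 to 37433246), rose from 107.8 ± 15.6 to 349.7 ± 45.2 CPM (SD, n = 3 each), a log2 change of 1.66 ± 0.16 (SE, edgeR quasi-likelihood, adjusted p = 0.0113). Trmt9b, a putative transfer RNA methyltransferase gene, rose by 2.16 ± 0.25 on the log2 scale and Sept4, a septin gene, by 1.01 ± 0.11 (both adjusted p = 0.0268, edgeR quasi-likelihood). Nrip2, which encodes a nuclear receptor interacting protein (chromosome 6, 128399296 to 128416427), fell from 50.1 ± 6.60 to 14.1 ± 1.51 CPM, a log2 change of -1.87 ± 0.16 (edgeR quasi-likelihood, adjusted p = 0.0067). Sec24d, a coat protein gene of vesicles that leave the endoplasmic reticulum, fell from 72.1 ± 14.2 to 22.1 ± 1.77 CPM, a log2 change of -1.74 ± 0.17 (edgeR quasi-likelihood, adjusted p = 0.0136).

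The other lower genes included a pair of sulfotransferases of extracellular glycans, Hs6st1 for heparan sulfate at -1.22 ± 0.14 and Chst15 for chondroitin sulfate at -1.07 ± 0.14, and a pair of mitochondrial transporters, Abcb10 at -1.91 ± 0.23 and Slc25a42 at -1.28 ± 0.16. Ripor2 had -1.09 ± 0.13 and Vps37b, of the endosomal sorting machinery, -1.39 ± 0.18, and adjusted p for these 6 lay between 0.0268 and 0.0442 by edgeR's quasi-likelihood test. With the replicate block, whose pairing was drawn from these same data, all 12 called genes stayed called, and further genes passed. In that fit these included Skil at -1.91 ± 0.20 (blocked adjusted p = 0.0118), Klf10 at -2.12 ± 0.20 (0.0066), Neurod2, a transcription factor of granule neurons, at -1.70 ± 0.16 (0.0066), Wnt7a at 1.74 ± 0.16 (0.0066) and Npnt at -1.26 ± 0.12 (0.0085). They also included the metabotropic glutamate receptor Grm2 at -0.92 ± 0.10 (0.0111), the T-type calcium channel Cacna1h at -0.79 ± 0.11 (0.0286), Fstl4 at -0.94 ± 0.14 (0.0328) and Inha, a subunit gene of inhibin, at 0.71 ± 0.12 (0.0488). None of these passed without the block, with adjusted p from 0.102 for Wnt7a to 0.244 for Fstl4 and Inha.

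Of the 15034 genes tested in the vector comparison, edgeR's quasi-likelihood test called 12, 4 higher and 8 lower. With the replicate block it called 141 (46 higher, 95 lower), and DESeq2 called 247 (76 higher, 171 lower), the 12 genes being among both sets and 113 of the 141 among the DESeq2 calls. At unadjusted p under 0.05 there were 1429 genes, 653 higher and 776 lower, where 752 are expected by chance, and scaling by library totals moved the higher share of these from 45.7% to 56.8%. The groups did not overlap for 16.5% of genes, where chance gives 10%. The count was 29 without GFP M1, 4 without GFP M2, 2 without Fst M1, 1 without Fst M2 and 3 without Fst F. It was 10 without GFP F, where 5 of the 12 genes stayed called, and 7 with the rRNA share of the library as a term. Of the 11 genes besides Fst, Nrip2 stayed called in all fits but those without Fst M1 (adjusted p = 0.0619) and Fst M2 (0.0738), and Robo3 in all but those and the fit without GFP M2 (0.0619, 0.0877 and 0.0769). Sec24d lost its call without Fst M1, Fst M2 or Fst F (0.0866, 0.179 and 0.0773). Abcb10 lost it without Fst M1, Fst M2, Fst F or GFP M2 (0.240, 0.179, 0.0988 and 0.0550), and Vps37b whichever of the 6 libraries was left out (0.0540 to 0.179). When 1 library was left out, the other 6 kept theirs only without GFP M1. With the rRNA share as a term Trmt9b, Hs6st1, Ripor2, Abcb10, Slc25a42, Chst15 and Vps37b lost their calls (0.0631 to 0.135). Their log2 changes with the term, in the same order, were 2.02, -1.26, -1.05, -1.77, -1.18, -1.01 and -1.31, near those without it. A tested minimum change of 1.2 fold ended those of Ripor2, Slc25a42, Chst15 and Vps37b (0.0529 to 0.0870), and leaving out both F libraries those of Sept4, Ripor2, Chst15 and Vps37b (0.0580 to 0.0848). Offsets for GC content and length ended those of Ripor2 (0.0561) and Chst15 (0.0532), and scaling by library totals that of Vps37b (0.0511). Over all alternatives adjusted p ran from 5.09e-17 to 0.0738 for Nrip2, from 8.58e-18 to 0.0877 for Robo3, from 5.33e-14 to 0.179 for Sec24d, from 6.66e-11 to 0.240 for Abcb10 and from 8.75e-08 to 0.179 for Vps37b. For the other 6 the highest lay between 0.179 and 0.212.

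Of the 40 gene lists, 8 moved in the vector comparison by camera with the preset correlation, 4 higher and 4 lower, and 10 with the replicate block. With an estimated correlation 0 passed, and 0 did so unadjusted. By fry 0 passed and 1 did so unadjusted. The adjusted p = 0.696 with an estimated correlation was the same for each of the 8. Genes that respond to SMAD signalling, which activins, BMPs and TGF-beta drive, were lower in 16 of 21 members (camera adjusted p = 0.0069, adjusted p = 0.696 with an estimated correlation). Adjusted over the list alone, 5 were lower and 0 higher, and 0 were called over all genes without the block. These were the feedback regulators Skil at -2.00 ± 0.35 (with the block -1.91 ± 0.20, adjusted p = 0.0118 over all genes), Smad7 at -0.97 ± 0.22, Ski at -0.57 ± 0.14 and Ldlrad4 at -1.23 ± 0.33, and Pmepa1 at -2.96 ± 0.70, named after its values were seen. Over all genes Pmepa1 had adjusted p = 0.2995 and Ldlrad4 0.281, and with the block 0.176 and 0.153. Pmepa1 stood at 34.4, 35.0 and 146.4 CPM in GFP M1, M2 and F and at 8.51 to 11.2 CPM with the Fst vector; without GFP F its log2 change was -1.90 (adjusted p = 0.0156 over all genes, edgeR quasi-likelihood) and that of Ldlrad4 -0.79 (0.413). Without each other library in turn Pmepa1 had adjusted p from 0.187 to 0.771. Skil stood at 91.4, 96.6 and 208.4 CPM in GFP M1, M2 and F and at 35.8, 27.5 and 38.4 CPM in the Fst vector libraries. The list kept its call without any 1 of the 6 libraries. Pathway ligands, receptors and antagonists did not pass as a list (43 members, adjusted p = 0.235), with 2 higher, Gdf11 at 0.77 ± 0.16 and Inha, and 1 lower, Fstl4, adjusted over the list alone.

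**Figure D3:**
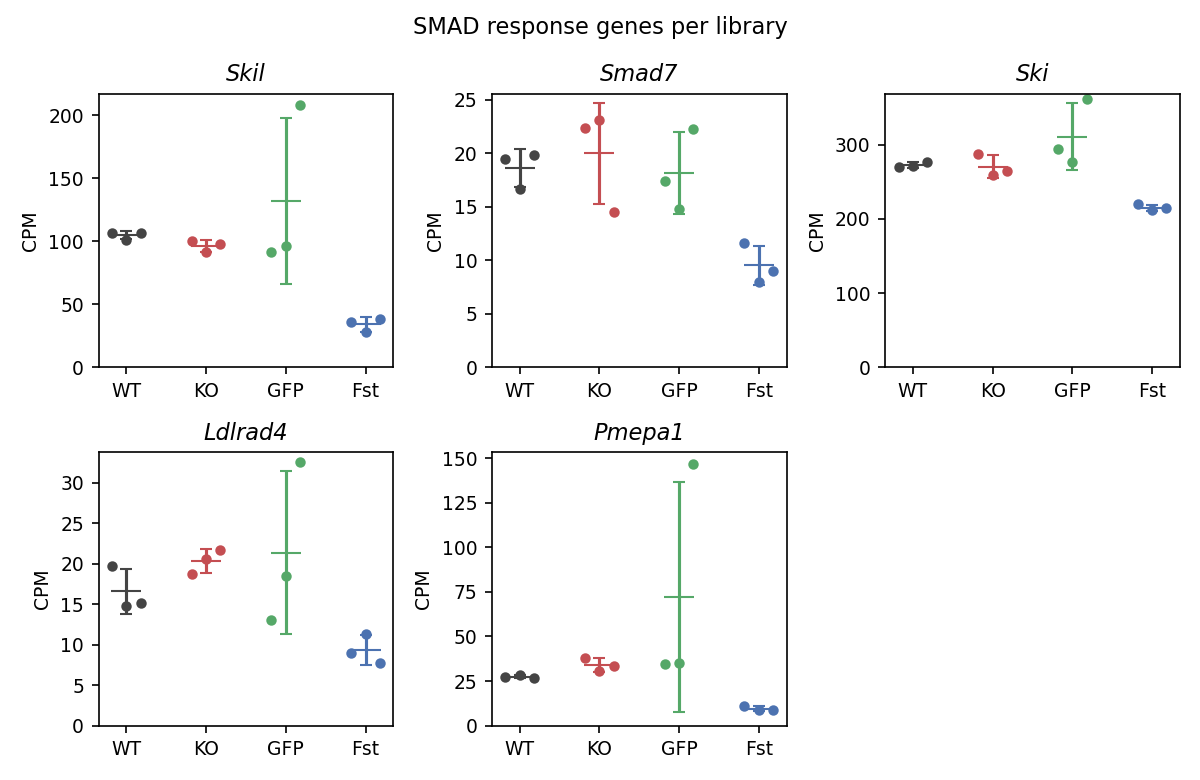
Levels of Skil, Smad7, Ski, Ldlrad4 and Pmepa1, all members of the SMAD response list, in CPM on linear axes, for the 4 groups, with a point per library and a dash and error bar at the mean and SD (n = 3). Skil lies at 91.4 CPM or above with the GFP vector and at 38.4 CPM or below with the Fst vector.

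Glial and immune lists moved in the vector comparison too, and the library GFP F stood above the mean of the other GFP vector libraries in reactive astrocyte, interferon response and antigen presentation genes. Interferon response genes were lower in 31 of 32 members (camera adjusted p = 2.49e-06, adjusted p = 0.696 with an estimated correlation), with Bst2 at -1.94 ± 0.56 and Irf7 at -2.54 ± 0.73. Reactive astrocyte genes were lower in 14 of 14 members (camera adjusted p = 0.0029, adjusted p = 0.696 with an estimated correlation), with Serpina3n at -3.23 ± 0.98, C4b at -1.33 ± 0.49 and Gfap, an intermediate filament of astrocytes, at -1.66 ± 0.80. Microglia markers were lower in 18 of 19 members (camera adjusted p = 8.06e-05, adjusted p = 0.696 with an estimated correlation), with Selplg at -0.53 ± 0.16 and Laptm5 at -0.50 ± 0.18. In each of these 3 lists 0 members passed adjusted over the list alone. Gfap stood at 566, 1555 and 4864 CPM in GFP M1, M2 and F, and at 613, 620.0 and 1033 CPM in Fst M1, M2 and F. Over the mean of the other GFP vector libraries, GFP F had a median log2 ratio of 2.48 ± 1.15 (SD) for 17 reactive astrocyte genes, 1.72 ± 0.779 for 35 interferon response genes, 0.873 ± 0.366 for 19 antigen presentation genes, 0.242 ± 0.310 for 19 microglia markers and 0.497 ± 0.765 for 22 SMAD response genes. The reactive astrocyte list lost its call without GFP F (adjusted p = 0.688), without Fst M1 (0.0552) and without both F libraries (0.355), and the interferon list lost its call without both F libraries (0.0527). Over all alternatives adjusted p ran from 6.27e-09 to 0.737 for reactive astrocytes and from 2.04e-13 to 0.737 for interferon response.

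By camera with the preset correlation, markers of other cell types were higher with the Fst vector. Of the 10 splits of the 6 libraries, 7 gave as many lists as the real 8, the real split included. Oligodendrocyte markers were higher in 15 of 17 members (camera adjusted p = 9.32e-04, adjusted p = 0.696 with an estimated correlation), with the myelin genes Mbp at 0.40 ± 0.13 and Cnp at 0.42 ± 0.13. Interneuron markers were higher in 16 of 22 members (camera adjusted p = 0.0069, adjusted p = 0.696 with an estimated correlation), with somatostatin (Sst) at 0.87 ± 0.29 and Dlx1 at 0.72 ± 0.22, and endothelial and mural markers in 16 of 19 (camera adjusted p = 0.0098, adjusted p = 0.696 with an estimated correlation), with Slco1a4 at 0.47 ± 0.16. Cytosolic ribosomal protein genes, which made up 2.08% of the counts in Fst M1 and 1.32 to 1.48% in the other vector libraries, were higher in 80 of 90 members (camera adjusted p = 3.66e-06, adjusted p = 0.696 with an estimated correlation), with Rpl21 at 0.48 ± 0.18, although copies elsewhere in the genome share its reads. That list was taken by symbol prefix and also holds the kinase gene Rps6ka6 at 0.90 ± 0.29. In each of these 4 lists 0 members passed adjusted over the list alone. The ribosomal list lost its call without Fst M1 (adjusted p = 0.758), endothelial markers without GFP M1 (0.278) or GFP M2 (0.0726), interneuron markers without GFP M1 (0.0902) or Fst M2 (0.122) and oligodendrocyte markers without GFP M1 (0.0902) or Fst F (0.0501). Over all alternatives the highest adjusted p of these 4 lists lay between 0.737 and 0.776 and the lowest between 1.67e-14 and 2.67e-04. The number of lists was 5 without GFP M1, 15 without GFP F, 15 without both F libraries and 14 with the rRNA share as a term.

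With the replicate block, glutamate receptors and meningeal fibroblast markers were also lower (both blocked adjusted p = 0.0464, against 0.0724 and 0.153 without it). Both had adjusted p = 0.737 with an estimated correlation and the block. Adjusted over the list alone, the glutamate receptor list had 2 lower members, Grm2 and the NMDA receptor subunit gene Grin2a at -0.67 ± 0.15. Other lists did not pass by camera but had members past the test adjusted over the list alone. Channels had 1 lower, Cacna1h (adjusted p of the list = 0.0587), GABA receptors 2 lower (0.228), and thalamus and habenula 2 higher and 1 lower (0.228). Neuropeptides and growth factors had 2 higher, with Wnt7a (0.272), CA1 pyramidal cells 2 lower (0.406), and CA3 and CA2 pyramidal cells 1 higher and 1 lower (0.474). Newborn neurons had 2 lower, with Neurod2 (0.4996), and striatum 1 higher (0.548). Mature granule cells had 2 higher and 1 lower, Npnt, immediate-early genes 2 higher and 1 lower, Klf10, and neocortex 1 lower (0.820 for each list). The lists with 0 such members were meningeal fibroblast, neural stem cell (0.0676), antigen presentation (0.0837), glucocorticoid response (0.0837), heat shock (0.0983) and oxidative phosphorylation (0.0983). So were monoamine receptors (0.143), blood (0.143), histones (0.1805), synaptic vesicle release (0.228), mossy cell (0.228) and astrocyte (0.272). So were proliferation (0.505), mitochondrially encoded (0.573), ependymal (0.646), choroid plexus (0.772), oligodendrocyte precursor (0.807), Cajal-Retzius (0.820) and Wnt and Notch response (0.945).

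The comparisons were then set against each other, to ask whether genes moved in opposite directions with loss of Fst and with the Fst vector. The 1 gene called in both was Fst, lower in KO and higher with the vector as the design sets it, so this overlap says nothing of other genes. Without GFP M1, 2 genes were called in both in opposite directions, Fst included. Across the 14575 genes tested in both, without Fst, the log2 changes had Pearson r = -0.0828 and Spearman rho = -0.0758, where genes are not independent replicates. Pearson r was -0.0482 without KO M1 and -0.0537 without WT F1. At unadjusted p under 0.05 in both, 79 genes went in opposite directions, 50 higher in KO and lower with the Fst vector and 29 the reverse, and 31 went in the same direction, where 41.6 are expected for independent lists in each case. Fisher's exact test of the overlap in either direction gave a one-sided p = 0.0012 and does not test the direction. With the replicate block in the vector comparison there were 134 opposite and 49 in the same direction. The 79 fell to 53 without WT M2 and rose to 120 without GFP M1, and the 31 fell to 15 without WT M2 and 20 without KO F1 and rose to 47 without GFP M1. Some genes were singled out here after their values were seen. Acvr1c had 0.43 ± 0.09 in KO and -1.93 ± 0.68 with the Fst vector (adjusted p = 0.475, with the block -1.85 ± 0.27 and 0.0475), and Cdhr1 -0.64 ± 0.14 and 1.29 ± 0.24 (adjusted p = 0.1385, with the block 1.31 ± 0.22 and 0.0487), by edgeR's quasi-likelihood test. In the same order there were Pmepa1 at 0.33 ± 0.10 and -2.96 ± 0.70, Ldlrad4 at 0.31 ± 0.12 and -1.23 ± 0.33, Asic4 at -0.89 ± 0.13 and 2.40 ± 0.55, and Hpca at 0.32 ± 0.06 and -0.80 ± 0.27. None of these 4 passed in the vector comparison, with adjusted p = 0.2995, 0.281, 0.267 and 0.413, or with the block, with 0.176, 0.153, 0.134 and 0.0514. Without GFP F the vector values were -1.90 for Pmepa1 (adjusted p = 0.0156), -0.79 for Ldlrad4 (0.413) and -1.25 for Acvr1c (0.759), and without GFP M1 they were 3.22 for Asic4 (0.0087), 1.57 for Cdhr1 (0.0408) and -0.45 for Hpca (0.416). In the other 5 fits without 1 library adjusted p ran from 0.187 to 0.771 for Pmepa1, from 0.242 to 0.702 for Asic4 and from 0.212 to 0.576 for Cdhr1. Sox1 had 0.16 ± 0.21 with the Fst vector (adjusted p = 0.854). Among the genes singled out, the libraries of the vector groups overlapped for Acvr1c, Hpca and Sox1. Skil, lower with the Fst vector, stood at 91.3 to 100.4 CPM in KO and at 101.3 to 106.6 CPM in WT. It thus did not go in opposite directions, unlike Pmepa1 and Ldlrad4 of the same list.

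**Figure D4:**
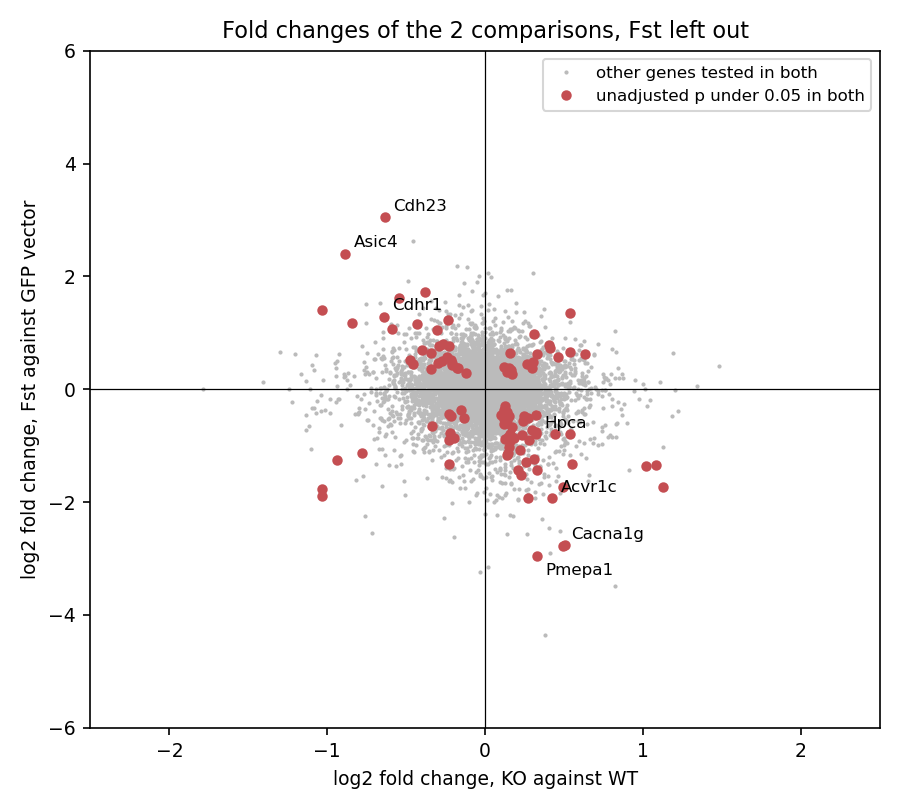
Log2 change of each gene in KO against WT (horizontal) and in Fst vector against GFP vector (vertical), with Fst left out and genes at unadjusted p under 0.05 in both comparisons in colour. Of the coloured genes 78 lie in the quadrants of opposite sign and 31 in those of the same sign.

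A test of the difference between the effects, over all 12 libraries, called 44 of 15632 genes, 12 with a higher change under the Fst vector than in KO and 32 with a lower one. Fst had the smallest p, followed by Nrip2 with a difference of -1.96 ± 0.18, Robo3 at 1.57 ± 0.17 and Sec24d at -1.76 ± 0.20 on the log2 scale (edgeR quasi-likelihood, adjusted p = 1.53e-04, 0.0010 and 0.0012). In KO against WT, Nrip2 had 0.08 ± 0.09, Robo3 0.08 ± 0.07 and Sec24d 0.00 ± 0.08. DESeq2 called 240 genes for this difference. The fit with the replicate block called 289. Leaving out KO libraries gave 13 genes without M1, 23 without F1 and 25 without M2. Leaving out WT libraries gave 19 without M1, 14 without F1 and 18 without M2. Among vector libraries there were 183 without GFP M1, 99 without GFP M2, 75 without GFP F and 29 without Fst M2.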

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

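The contrast used here, follistatin present minus follistatin absent in both tables, and its selection of genes called in the vector comparison were chosen after the data were seen. It asks whether the Fst vector and the endogenous gene moved a transcript alike. The 12 genes given here had effects that differed between the tables in a fit of all 12 libraries (edgeR quasi-likelihood). They were selected by their change in the same vector libraries, which favoured a difference, so these values are no independent test of it. For Fst the vector itself sets the change, and its size rests on 1 count over the GFP vector libraries. Regroupings of the libraries were not run for this contrast. The log2 difference was 8.18 for Fst (adjusted p = 4.45e-04). It was 1.74 for Robo3 (4.45e-04), 0.92 for Sept4 (0.0125) and 2.03 for Trmt9b (0.0378). It was -1.79 for Nrip2 (4.45e-04), -1.74 for Sec24d (0.0013), -1.20 for Hs6st1 (0.0098), -1.06 for Ripor2 (0.0071), -1.83 for Abcb10 (0.0119), -1.03 for Slc25a42 (0.0463), -1.04 for Chst15 (0.0119) and -1.22 for Vps37b (0.0455). This contrast called 17 genes, 5 higher and 12 lower. Groups of 3 libraries were too small for the test of single libraries far from the rest.

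For the difference between the KO effect and the Fst vector effect, 3 of 60 drawn regroupings within the tables, the real one included, called as many genes as the real 44 in the fit without the replicate block, with 66 as the highest of the others, so chance cannot be excluded for that count. Of the 32 regroupings with the block that part all pairs in each table, the real one called 289 genes and the highest other 269. The 7 others that kept the real vector groups called 152 to 269 genes and the remaining 24 at most 1. A count of this size thus rests mainly on the vector groups, whose 4 splits that part all pairs are too few to exclude chance. Between KO and WT the block used the replicate names, where no pairing was assumed. Chance therefore cannot be excluded for that count either.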

How the results depend on the processing

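Settings with the rRNA share, GC and length offsets, both F libraries left out or the present-against-absent contrast were chosen after the data were seen. So were the list test with an estimated correlation and the block, and all settings of GFP vector against KO. The leave-one-out and rRNA settings of the difference of effects were chosen then too. No called value changed direction; Sec24d in KO against WT, near 0 and not called, had -0.013 with scaling by library totals and -0.0588 to 0.084 without 1 library, below 0 without KO M1, WT F1 or WT M2. The higher share at unadjusted p under 0.05 in the vector comparison turned from 45.7% to 56.8% with library totals. Fst kept its direction and call under every setting run, with log2 changes of -4.13 to -3.52 in KO and 11.4 to 13.8 with the vector when 1 library was left out. The 4 genes of KO against WT became 46 without a filter, 30 with sex by title, 8 with GC and length offsets, 2 with a tested minimum change, 1 with a spread shared over 12 libraries and 2 to 17 without 1 library. The replicate block gave 23; same-named libraries correlated at 0.0137, -0.0234 and -0.136, not every library correlated best with its own number, and no pairing was assumed there. The 9 lists became 0 with an estimated correlation, 0 by fry and 7 to 14 without 1 library, and stayed 9 with the block. The 12 genes of the vector comparison became 247 by DESeq2, 230 without a filter, 141 with the replicate block, 132 with sex by title or description, 412 with a spread shared over 12 libraries, 7 with the rRNA term, 185 with offsets and the block, 27 without both F libraries and 1 to 29 without 1 library. The 8 lists became 14 with the rRNA term, 15 without both F libraries, 0 with an estimated correlation, 0 by fry, 0 with an estimated correlation and the block, and 5 to 15 without 1 library. The block changed no call of a list other than glutamate receptors and meningeal fibroblasts. The correlation between comparisons was -0.66 over the 3 genes besides Fst called in KO against WT, too few to read, -0.54 over the 11 called in the vector comparison, and -0.099 to -0.0482 without 1 library. Genes called in both in opposite directions numbered 79 at unadjusted p under 0.05, 2 by DESeq2, 4 with the block in each fit, and 1 to 2 without 1 library. The difference of effects had 240 genes by DESeq2, 289 with the replicate block, 17 with the present-against-absent contrast and 13 to 183 without 1 library. GFP vector against KO had 279 genes in its own 6 libraries, 65 with offsets there, and 7 to 1831 without 1 library. Scaling moved no median by over 0.1. Values of named genes kept direction and side of the threshold in 784 cases in KO against WT and 775 in the vector comparison, passed it newly in 54 and 104 and lost it in 13 and 66; called lists kept theirs in 81 and 77 and lost it in 27 and 35. Where an alternative leaves out a library it has fewer samples; for the other moves the cause was not tested. On simulated data 4.5% of changes of 1.5 fold were recovered in the vector comparison and 67.2% in KO against WT, where the biological coefficients of variation were 0.208 and 0.0884. Depth limits the ratios of Fst, with 8 counts over the KO and 1 over the GFP vector libraries.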

Other observations

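The tests of mitochondrial RNA, astrocyte number, sex and table were chosen after the results they bear on were seen, and the offsets for GC content with length after the data were seen; for shared rRNA words, neighbouring tissue and other splits of the libraries, what would decide was written before the result. The splits with the block over both comparisons were added after the other results were seen.

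Some transcripts, chosen after their values were seen and with no test, had different levels in libraries of the same vector group. Penk, the enkephalin precursor, stood at 22.4, 252 and 479 CPM in GFP M1, M2 and F and at 58.5, 52.6 and 519 CPM in Fst M1, M2 and F, against 9.002 to 20.7 CPM in KO and WT. Nptx2 stood at 24.9, 70.4 and 223 CPM with the GFP vector and at 26.7, 16.5 and 131 CPM with the Fst vector, and Bdnf at 73.4, 125 and 208 CPM and at 75.6, 76.1 and 192 CPM. Inhba, an activin subunit gene, stood at 10.5, 17.8 and 90.2 CPM and at 6.97, 10.6 and 36.9 CPM. Calb1, the calbindin of granule cells, went the other way, at 234, 135 and 67.8 CPM and at 212, 201 and 93.9 CPM. Igkc, an antibody light chain gene, stood at 24.7, 1.85 and 1.15 CPM with the GFP vector and at 99.9, 6.89 and 35.6 CPM with the Fst vector, and at 0.535 CPM or less in each KO and WT library.

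A first pattern was a set of 24 genes, all higher in KO M2, WT F1, GFP M2, Fst M2 and Fst F, the 5 libraries with rRNA; they included Hsp90aa1, with a log2 difference of 4.97, Rpl12 at 3.43 and Rrp1 at 3.87, and all 8 tested genes with Rrp symbols were among them. Of 15 protein-coding genes, 0% shared an exact word of 25 bases with the 362 rRNA transcripts searched. This argues against depletion probes that reach these genes through exact matches to those transcripts. Inexact matches and rRNA outside those transcripts were not searched, so depletion in general stays open. Different amounts of mitochondrial RNA are argued against by a median log2 difference of 0.0244 ± 0.221 (SD) over 12 mitochondrial mRNAs. What sets these libraries apart stays open, and no biological explanation was tested.

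Another pattern was the reactive astrocyte list, highest in GFP F, with a median log2 ratio of 2.48 ± 1.15 (SD, 17 genes) over GFP M1 and M2, while GFP M2 also lay above GFP M1 in Gfap (1555 and 566 CPM), Serpina3n (128 and 54.9 CPM) and C4b (140.4 and 58.7 CPM). More astrocytes, as an account of the whole 2.48, are argued against by a median of 0.172 ± 0.482 over 19 other astrocyte markers. Aqp4, of the astrocyte list, rose all the same, at 102, 183 and 364 CPM in GFP M1, M2 and F. Levels per cell were not measured, so a smaller rise in astrocyte number stays open. Sex alone is argued against by the F libraries of the other groups, whose largest median was 0.295, in Fst F, also given a vector. Sex together with what sets the GFP vector group apart stays open. Tissue of a neighbouring region cannot be told apart, since the largest median among 5 such lists was 0.709 ± 0.726, for 4 ependymal genes. A response to injection or vector that differs between these libraries may account for it, untested.

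KO with the GFP vector differed from KO without a vector in 559 genes (331 higher, 228 lower) in the fit of 12 libraries and in 279 on their own 6 libraries; Shank3 had a log2 change of -1.31 ± 0.09 there. GC content and length may account for part: of the 279 genes, 59 (21.1%) stayed called with offsets, Shank3 among them at -1.34 ± 0.08. The 220 whose calls ended had the same sign with offsets, a median of 76.3 ± 15.3% (SD) of their log2 change and about the same SE (median 0.105), with adjusted p from 0.0509 to 0.396 (edgeR quasi-likelihood), and H2-D1, one of them, went from 1.37 ± 0.22 to 1.21 ± 0.22. The vector cannot be told apart from the table, since 0 vector libraries are in the other table. The 559 became 7 without KO M1, 20 without KO F1, 10 without KO M2, 160 without WT M1, 181 without WT F1, 162 without WT M2, 1831 without GFP M1, 131 without GFP M2, 141 without GFP F and 1481 without Fst M1.

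Splits of 6 libraries into 3 and 3 number 10, too few for a share under 0.05. In KO against WT, 2 splits gave as many genes as the real 4 (highest other 5) and 2 as many lists as the real 9 (highest other 12). In the vector comparison, 3 gave as many genes as the real 12 (highest other 27) and 7 as many lists as the real 8 (highest other 16). With the 6 KO and GFP vector libraries regrouped in the fit of all 12, 1, the real split, gave as many as the real 559 (highest other 0). The split with 27 genes set GFP M1, Fst M1 and Fst M2 against GFP M2, GFP F and Fst F. It points to a structure of the samples. The same split parted transcripts given above after their values were seen. Penk, Nptx2, Bdnf and Inhba were higher, and Calb1 lower, in GFP M2, GFP F and Fst F than in any other vector library. Igkc did not follow it. The split is uneven between the vector groups, so it is partly confounded with the vector comparison, and its cause was not tested. The split with 15 genes followed the rRNA share exactly, and with that share as a term the real comparison called 7 genes. Genes that lost their calls there had log2 changes near those without the term, such as -1.26 against -1.22 for Hs6st1 and -1.77 against -1.91 for Abcb10. With the replicate block, 1 of the 4 splits that part all 3 pairs, the real one, called as many as 141, and the others called 0. For the correlation between comparisons, 17 of 100 pairs of splits gave a size as large as 0.0828 (highest other 0.310), and for genes in opposite directions at unadjusted p under 0.05, 7 of 100 gave as many as 78, Fst left out (highest other 122). Those pairs took all 10 vector splits without the block, 6 of which part 1 pair of replicates. With the block and the 4 vector splits that part all 3 pairs, 9 of 40 pairs of splits gave a correlation as large as 0.0834 (highest other 0.121) and 2 of 40 as many genes as 133 (highest other 151, with the real vector split and another split of KO and WT). Chance cannot be excluded for either, with or without the block.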
